A study of Homo sapiens with 6 samples.

How the data were processed

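The samples were 6 poly(A)-selected RNA-seq libraries of MEG-01 cells, an established human megakaryoblastic leukaemia line. Per the labels, 3 libraries came from cells with the empty pLKO.1 vector (control) and 3 from cells with a short hairpin RNA against MELK (knockdown). Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

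The authors deposited 1 table of whole-number counts per gene, with columns named as raw in the file header. Per the submitters' processing notes, the tools named are FastQC, fastp, STAR, HTSeq, DESeq2 and R 4.3.3, with no roles, and the build is GRCh38. The counting mode, the strand setting and the annotation release are not given in the sources used here, so genes that share reads with a near-identical copy or an overlapping gene remain uncertain. The table held 61852 genes, of which 61803 had a symbol (99.9%). Coordinates are from GENCODE release 29 on GRCh38. Library totals ran from 18945176 to 21711313 counts.

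The deposited counts are not plain read counts at the low end. In 35797 genes (57.9%) every one of the 6 values was 0, 1, 2, 10 or 100, in nearly equal shares of 19.8%, 20.2%, 20.4%, 19.9% and 19.8%. The values were tested for independence between libraries in 15 pairs by chi-square, and the lowest adjusted p was 0.472, with a Cramér's V of at most 0.0137. The table behaves as a read count plus a number drawn from those 5. Where the number was added is unknown. It weighs on genes with few reads, since the 5 numbers have a SD of 38.9, and weighs less the more reads a gene has. The 5038 genes with a mean of at least 500 counts held between 87.7% and 88.9% of each library's total.

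The design was fixed before the data were examined. Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr at its default minimum count of 10, a robust quasi-likelihood F-test and no block, and Benjamini-Hochberg adjusted p below 0.05 as the threshold. The 29 gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, for lists with at least 5 tested members. The genes each list was compared with include genes without reads, which the filter let in. Camera with an estimated correlation and the rotation test fry were alternatives. Other alternatives were relative log expression, upper quartile and library-size scaling, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, non-robust dispersion, the replicate number as a block, a test against a fold change of 1.5, and each library left out in turn. With a library left out the filter let in more genes, 40268 to 40434 against 28303. Those fits therefore change both the libraries and the genes tested.

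3 further analyses were chosen after the values were seen. The first kept genes with a mean of at least 500 counts. The second modelled each value as a negative binomial read count plus a number drawn equally from 0, 1, 2, 10 and 100, with a dispersion of 0.00213 and a likelihood-ratio test, and it gave estimated reads per group with 95% profile intervals. The third removed each library's trend with GC content and transcript length from the genes with a mean of at least 500 counts, of which 99.9% had both. A scan of 7-base words in annotated 3′ UTRs used a linear model with UTR length and GC content, against 200 shuffles.

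Genes were named by a rule fixed before the data were examined. It took MELK, the 10 genes with the largest increase and the 10 with the largest decrease at a mean of at least 2 CPM, up to 4 members of each gene list, and a fixed set of megakaryocyte, ERK and cofilin genes. As written, the part on the largest changes took 20 genes with a mean of at most 50.7 counts, and 14 of them held only the 5 values above. These are not described. Some genes of the fixed set are not reported here. The same rule with a mean of at least 500 counts was used in their place, and that choice was made after the values were seen.

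The scripts were tested on simulated data. For the edgeR fit, changes were planted only in genes with medium to high counts. With the added number, the edgeR fit with filterByExpr on 30036 genes recovered 41.8%, 79.1% and 91.0% of genes changed by 0.5, 1 and 2 on the log2 scale, with 0 unchanged genes among 147 calls. With a mean of at least 500 counts, on 5150 genes, it recovered 97.9%, 100% and 100%, with 9 unchanged genes among 170 calls. In the first fit 55, 67 and 78 genes were changed, and in the second 47, 50 and 65. The data gave 4683 and 3877 calls. With fewer changed genes the adjusted threshold is stricter, so these shares and the counts of unchanged genes do not carry over to the data. The model of the added number, on 3000 genes, recovered 92.9%, 98.6% and 98.6% of changes of 1, 2 and 3, and it also called 16 unchanged genes. The GC and length correction, on 5031 genes with a simulated GC trend, took the number of unchanged genes called from 3529 to 7. The word scan placed a planted word lowest in 20 of 20 simulations on 4908 genes.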

Results

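RNA-seq counts were compared between MEG-01 megakaryoblasts carrying the empty pLKO.1 vector (n = 3) and MEG-01 cells carrying a short hairpin RNA against MELK (n = 3). MELK is a serine/threonine kinase expressed in proliferating cells. The series' title places the comparison in megakaryocyte formation and ERK and cofilin signalling. Library totals were 21468434, 20208255 and 21711313 counts in the control and 19553233, 20410845 and 18945176 in the knockdown. The deposited values appear to hold a number drawn from 0, 1, 2, 10 and 100 on top of each read count. For genes with few reads the single values as deposited are therefore unreliable.

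MELK (ENSG00000165304, GRCh38 chromosome 9, 36572862 to 36677683) had values of 219, 206 and 238 in the control libraries and 16, 124 and 26 in the knockdown libraries. Its mean level was 11.01 ± 0.521 CPM (SD, n = 3) in the control and 2.78 ± 2.94 CPM (SD, n = 3) in the knockdown. The log2 fold change was -1.98 ± 0.69 (SE), and MELK did not pass the threshold in edgeR's quasi-likelihood test (adjusted p = 0.104). Knockdown library 2 decided this. Without it the log2 fold change was -3.33 (edgeR adjusted p = 0.00286). With the added number modelled, a test chosen after the values were seen, the estimate was -3.38 (95% interval -3.85 to -2.96). MELK passed in 5 of the alternatives, with adjusted p of 0.0487 or less.

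**Figure D1:**
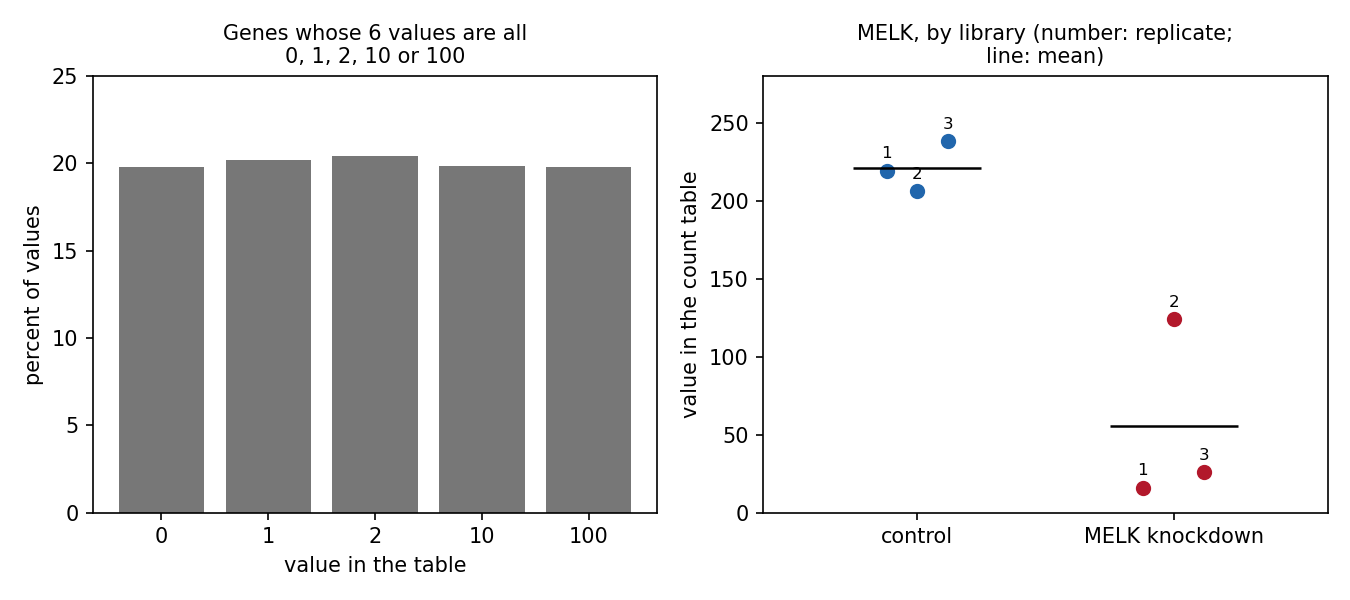
Left, the percentage of values equal to 0, 1, 2, 10 and 100 in the 35797 genes that hold no other value; each share lies between 19.8% and 20.4%. Right, MELK in each library as the value in the count table, with the replicate number beside each point and the group mean as a line; knockdown library 2 is at 124 and the other knockdown libraries are at 16 and 26.

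The knockdown libraries differed from the control libraries across the transcriptome. Of 28303 genes tested, 4683 passed the threshold, 2297 higher and 2386 lower in the knockdown (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). At least 2-fold changes were seen in 527 higher and 602 lower genes. Among genes with a mean of at least 500 counts, 1638 were higher and 1786 lower. Within groups, library correlations of log2 CPM over these genes were 0.994 to 0.996, and between groups 0.890 to 0.907. The first principal component held 94.0% of the variance. All 3 libraries of one group lay beyond all 3 of the other in 8695 of the tested genes (30.7%). Chance gives 10% for values without ties. Genes that hold only the 5 added values have tied counts, so 10% is a rough guide here. Across genes with a mean of at least 500 counts, log2 fold change was lower at higher GC content (Spearman rho -0.386). The filter let in 8895 genes that hold only the 5 added values, and 108 of these were among the calls. Of the 20 largest changes at a mean of at least 2 CPM, 14 were in such genes. The counts of at least 2-fold changes therefore include some of them.

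At a mean of at least 500 counts the largest increase was in TFPI2, a Kunitz-type serine protease inhibitor (chromosome 7, 93885396 to 93890991), which rose from 4.91 ± 0.144 to 203.7 ± 8.85 CPM (SD, n = 3), a log2 fold change of 5.37 ± 0.06 (SE). The protease inhibitor A2M rose by 4.24 ± 0.21, or by 5.11 with the added number modelled, as its control values were 124, 53 and 73. The collagenase MMP1 rose by 3.18 ± 0.14 and the tetraspanin-like surface protein TM4SF1 by 3.36 ± 0.08. CCNA1, cyclin A1, rose by 3.67 ± 0.12, TSPAN13 by 3.18 ± 0.27, the ERK phosphatase DUSP5 by 2.77 ± 0.14, the BH3-only gene PMAIP1 by 2.61 ± 0.10, ENC1 by 2.55 ± 0.06 and FAM83A by 2.54 ± 0.06. The largest decreases were in FAM30A (-2.99 ± 0.07), the phospholipase PLCB2 (-2.77 ± 0.07), the calcium-binding gene S100A4 (-2.73 ± 0.05), UNC5B (-2.72 ± 0.26), CLNS1A (-2.64 ± 0.09), EMID1 (-2.61 ± 0.20), C1orf43 (-2.60 ± 0.07), RAB37 (-2.54 ± 0.15) and the myeloid integrin ITGAM (-2.48 ± 0.09). The mast cell tryptase TPSAB1 fell as well (-2.73 ± 0.10), and its reads may be shared with its near-identical neighbour. With the added number modelled, CCNA1 was at 4.20, TSPAN13 at 3.59, UNC5B at -3.05 and EMID1 at -2.83. The modelled change was slightly smaller than the edgeR value for FAM30A, TPSAB1, S100A4, CLNS1A and ITGAM. All 20 genes passed the edgeR threshold with adjusted p of 0.000122 or less.

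**Figure D2:**
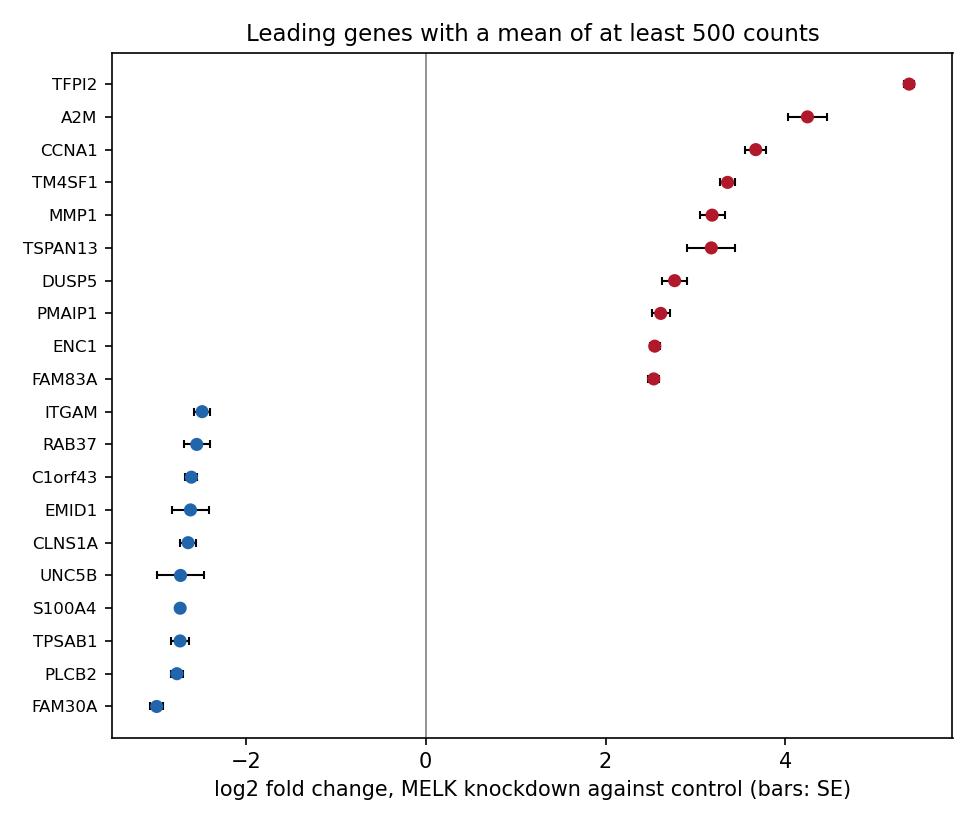
Log2 fold change of MELK knockdown against control (x axis), with SE bars, for the 10 genes with the largest increase (red) and the 10 with the largest decrease (blue) at a mean of at least 500 counts. TFPI2 lies at 5.37 and FAM30A at -2.99.

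Platelet and megakaryocyte genes moved both ways. Of 25 megakaryocyte and platelet markers tested, 7 rose, 3 fell and 15 did not pass. The platelet integrin genes ITGA2B (-0.93 ± 0.03, chromosome 17, 44372180 to 44389505) and ITGB3 (-0.70 ± 0.06) and the von Willebrand factor receptor gene GP1BA (-0.90 ± 0.13) fell. The granule proteoglycan SRGN (1.17 ± 0.09), the collagen receptor GP6 (0.52 ± 0.05) and LTBP1 (3.00 ± 0.17) rose. As a list they did not stand apart from other genes (camera adjusted p = 0.221). ITGA2B lost its call with limma-voom (adjusted p = 0.155). Counts of GP9, TUBB1 and PF4 were too low for the edgeR test to decide, PF4 was not tested, and the modelled estimates were -1.51 (95% interval -2.68 to -0.45) for GP9 and 0.50 (0.19 to 0.80) for TUBB1. For GP9 the sign differed from that of the edgeR fit (2.02 ± 1.51, adjusted p = 0.491). The simulated genes on which the model was tested started from more reads than GP9 has, so the model's error there is unknown.

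Of 19 megakaryocyte transcription factors tested, 5 rose, 10 fell and 4 did not pass. GATA1 (-0.56 ± 0.04), NFE2 (-0.47 ± 0.03), GFI1B (-0.57 ± 0.04), LYL1 (-1.04 ± 0.05) and LDB1 (-0.91 ± 0.04) fell, while TAL1 (0.87 ± 0.03) and FLI1 (0.68 ± 0.08) rose. The list passed camera in the downward direction (adjusted p = 0.00874). The call was lost with an estimated correlation (adjusted p = 0.245), at a mean of at least 500 counts (adjusted p = 0.236) and with the filter of 5 CPM in 3 libraries (adjusted p = 0.0975). Of 22 platelet granule genes tested, 4 rose, including SNAP23 (1.06 ± 0.05) and RAB32 (0.94 ± 0.05), and 5 fell, including UNC13D (-0.81 ± 0.04) and HPS1 (-0.93 ± 0.10).

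Of 22 erythroid markers tested, 10 fell, 1 rose and 11 did not pass (camera adjusted p = 2.01e-06, downward). The list's call was lost with an estimated correlation (adjusted p = 0.0727). Adjusted over the list alone, 11 were lower and 1 higher. The erythroid factor KLF1 fell by 1.45 ± 0.06, the Rh-associated glycoprotein RHAG by 1.92 ± 0.07 and the membrane ankyrin ANK1 by 1.00 ± 0.03. HBA2 fell by 2.31 ± 0.12, and its reads may be shared with HBA1. The 3′ UTR of RHAG holds the 7-base word TGACTAT, which was associated with lower expression across genes, and so do those of ITGB3, XBP1, MCM3, RACGAP1, SSH1 and DUSP6. Granulocyte and monocyte markers gave 2 higher and 3 lower of 16. SPI1 fell by 1.13 ± 0.05 and CD33 by 0.50 ± 0.04, while FCGR1A rose by 2.79 ± 0.25. Among mast cell markers, HDC fell by 0.56 ± 0.03 and FCER1A rose by 1.15 ± 0.08 and CPA3 by 0.90 ± 0.12 (2 higher, 3 lower of 10). In the stem and progenitor list, KIT rose by 2.93 ± 0.13 and ERG by 1.07 ± 0.08 (3 higher, 2 lower of 13). CD4 was the 1 of 10 lymphocyte markers past the threshold (-1.70 ± 0.04). Of 11 stromal and endothelial markers, 3 rose and 1 fell, with ESAM at 0.48 ± 0.03 and PECAM1 at 0.47 ± 0.06.

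Of 17 cyclin-dependent kinase inhibitors and antiproliferative genes, 8 rose, 0 fell and 9 did not pass (camera adjusted p = 2.01e-06, upward). This call was lost with an estimated correlation (adjusted p = 0.0727). CDKN1A rose by 1.81 ± 0.05, GADD45A by 1.95 ± 0.07, CDKN2B by 1.98 ± 0.13 and BTG2 by 0.80 ± 0.05. Of 35 genes of G2/M and mitosis, 11 rose and 3 fell (camera adjusted p = 0.0258, upward, and 0.245 with an estimated correlation). KIF20A rose by 1.29 ± 0.06, CKS2 by 1.36 ± 0.05 and BIRC5 by 0.48 ± 0.04, and RACGAP1 fell by 0.69 ± 0.08. This call was lost when control replicate 2 or any 1 of the knockdown replicates was left out (adjusted p of 0.0531 to 0.131), at a mean of at least 500 counts (0.0959) and with the filter of 5 CPM in 3 libraries (0.0975). The fits without a library also compared the list with more genes. Replication genes went both ways, with 8 higher and 10 lower of 36, and CDT1 (-0.96 ± 0.04), MCM5 (-0.82 ± 0.04) and MCM3 (-0.85 ± 0.05) fell. Of 23 p53 targets, 5 rose, among them CDKN1A and GADD45A, and 5 fell, among them TP53INP1 (-1.76 ± 0.13), and at a mean of at least 500 counts 7 rose and 3 fell of 12.

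Of 24 ERK-responsive genes, 9 rose, 3 fell and 12 did not pass (camera adjusted p = 0.00874, upward). This call was lost with an estimated correlation (adjusted p = 0.245), at a mean of at least 500 counts (adjusted p = 0.446) and with the filter of 5 CPM in 3 libraries (adjusted p = 0.161). Of the 12 members with a mean of at least 500 counts, 5 rose and 4 fell. Their median log2 fold change was 0.10, against 0.65 over all 24. DUSP5, DUSP6 (0.89 ± 0.10), FOSL1 (1.09 ± 0.06) and IER3 (1.03 ± 0.08) rose and MYC fell by 0.95 ± 0.04. Of 25 cascade components, 5 rose and 8 fell (camera adjusted p = 0.266). MAPK3, which encodes ERK1, fell by 1.65 ± 0.05 (chromosome 16, 30114105 to 30123506) and the RAF inhibitor PEBP1 by 1.13 ± 0.03. MAP2K2 fell by 0.62 ± 0.04 and SHC1 by 0.67 ± 0.03.

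Genes of cofilin regulation and actin turnover gave 9 higher and 8 lower of 31 (camera adjusted p = 0.587). CFL1, the main cofilin gene (chromosome 11, 65823022 to 65862026), was at 1693 ± 24.6 CPM in the control and 1896 ± 49.7 CPM in the knockdown (SD, n = 3), a log2 fold change of 0.16 ± 0.03 (SE, edgeR adjusted p = 0.00272). Its call was lost in 5 of the 6 fits that left out a library, with log2 fold changes of 0.09 to 0.19. Those fits also tested more genes, so the loss may not come from the missing library alone. The cofilin phosphatase SSH1 rose by 1.12 ± 0.08 and the actin recycling gene CAP1 by 1.42 ± 0.05, while TWF2 fell by 1.06 ± 0.05 and RAC2 by 0.47 ± 0.03. LIMK1 (-0.01 ± 0.05) and LIMK2 (0.07 ± 0.05), which encode cofilin kinases, did not pass (adjusted p = 0.996 and 0.486). CFL2 had too few reads for the edgeR test (0.94 ± 0.56, adjusted p = 0.371), and the model gave 1.88 (95% interval 1.58 to 2.21).

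Cytoskeletal genes of proplatelet formation leaned upward, with 12 higher and 9 lower of 28 (camera adjusted p = 0.0138, and 0.394 with an estimated correlation). The spectrins SPTAN1 (2.02 ± 0.07) and SPTBN1 (1.47 ± 0.06), the tropomyosin TPM4 (0.95 ± 0.05) and the non-muscle myosin MYH9 (0.65 ± 0.03) rose. Leaving out control replicate 2 or any 1 of the knockdown replicates, which also let in more genes, ended the list's call (adjusted p of 0.0546 to 0.131). Of 17 SRF and MRTF targets, 4 rose and 3 fell, with VCL at 1.17 ± 0.07 and PDLIM7 at -1.60 ± 0.13. Integrin and adhesion genes gave 10 higher and 7 lower of 27. The leukocyte integrins ITGAL (-2.19 ± 0.08) and ITGB2 (-2.20 ± 0.07) and the kinase LYN (-1.82 ± 0.04) fell, and CD44 rose by 1.11 ± 0.03.

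**Figure D3:**
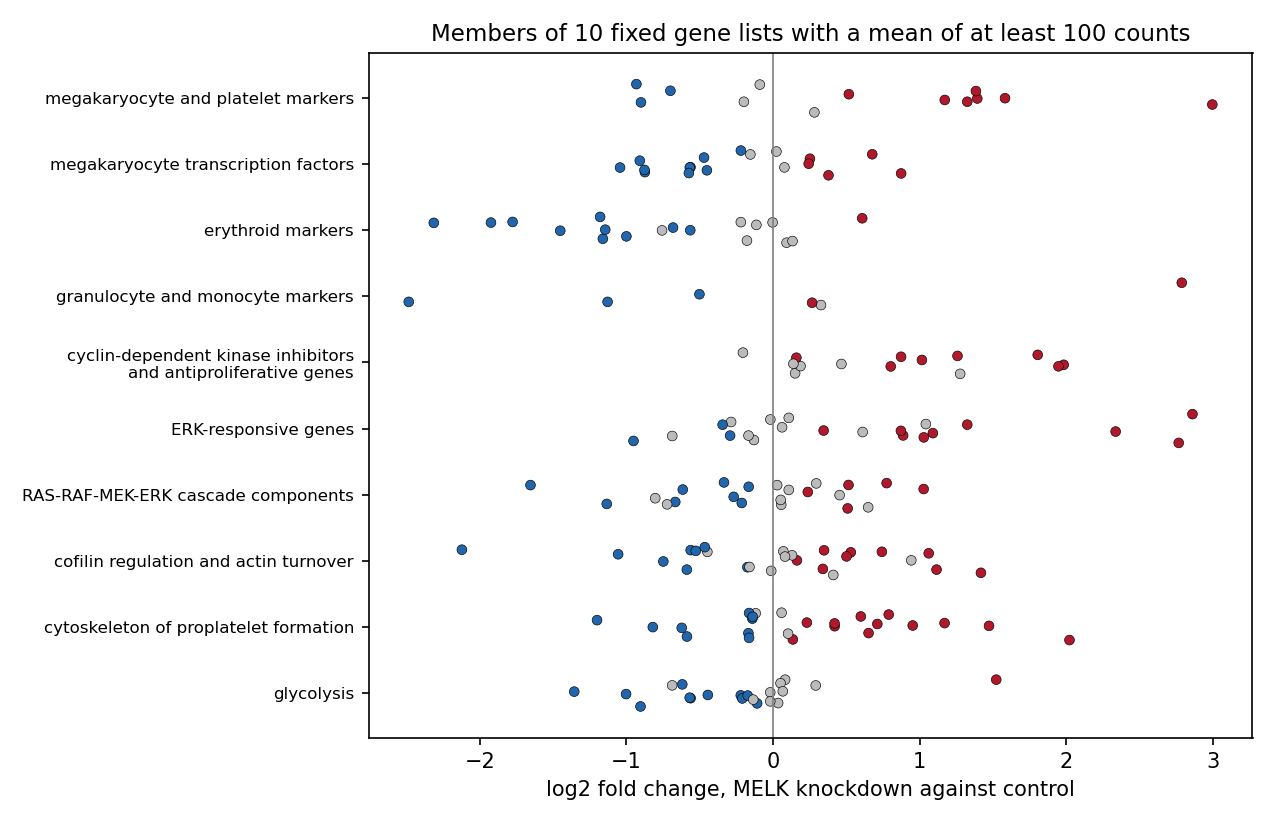
Log2 fold change of MELK knockdown against control (x axis) for members of 10 fixed gene lists with a mean of at least 100 counts. Each point is 1 gene, red where it rose past the threshold, blue where it fell past it and grey where it did not pass; vertical position within a list is arbitrary. Erythroid markers lie mostly to the left and cyclin-dependent kinase inhibitors to the right.

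Of 21 glycolysis genes, 11 fell and 1 rose (camera adjusted p = 3.09e-05, and 0.245 with an estimated correlation), with GAPDH at -0.62 ± 0.02, GPI at -0.56 ± 0.03 and the glucose transporter SLC2A3 at 1.52 ± 0.05. Of 13 mitochondrially encoded genes, 11 fell and 0 rose (camera adjusted p = 1.10e-09, and 0.245 with an estimated correlation), with MT-ND3 at -0.58 ± 0.04 and MT-CO3 at -0.45 ± 0.03, and the mitochondrial share of counts was 10.2% to 10.7% in the control libraries and 9.12% to 9.18% in the knockdown libraries. Of 23 genes of the unfolded protein and integrated stress response, 11 fell and 5 rose (camera adjusted p = 0.00890, and 0.245 with an estimated correlation), including the serine synthesis enzyme PHGDH (-1.64 ± 0.04), ATF4 (-0.56 ± 0.03) and XBP1 (-1.28 ± 0.06), while PPP1R15A rose by 0.55 ± 0.03. At a mean of at least 500 counts the adjusted p of these 3 lists was 0.191, 0.0959 and 0.0959.

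The remaining lists did not pass camera. Thrombopoietin and JAK-STAT genes gave 5 higher and 9 lower of 21, with BCL2L1 at -0.75 ± 0.04 and JAK1 at 0.72 ± 0.05. Cholesterol synthesis genes gave 4 higher and 10 lower of 25, with SQLE at 0.72 ± 0.06 and LSS at -0.68 ± 0.05. BCL2 family genes gave 6 higher and 5 lower of 17, with MCL1 at 0.84 ± 0.05 and BBC3 at -0.61 ± 0.05. Type I interferon genes gave 1 higher and 2 lower of 26, with STAT2 at -0.47 ± 0.06, and 5 higher and 15 lower of 29 with the added number modelled. NF-κB genes gave 4 higher and 3 lower of 21, with CCL2 at 1.70 ± 0.12, NFKB2 at -0.38 ± 0.05 and NFKBIA at -0.48 ± 0.06. At a mean of at least 500 counts 1 NF-κB gene was higher and 5 were lower of 7, and with the added number modelled 9 were higher and 5 lower of 22. Ribosome biogenesis genes gave 6 higher and 5 lower of 23, with NOLC1 at 0.79 ± 0.07. Of 10 reported MELK partners and substrates, 3 rose and 2 fell, with STRAP at 0.75 ± 0.08 and EIF4B at -0.64 ± 0.06.

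The counts above are over all genes tested. Adjusted over the list alone, the number of members past the threshold differed in these lists. It was 3 higher and 3 lower for granulocyte and monocyte markers, 4 and 1 for stromal and endothelial markers, 8 and 12 for replication, 7 and 6 for p53 targets, 11 and 4 for ERK-responsive genes, 6 and 8 for cascade components and 11 and 9 for cofilin regulation. It was 13 and 10 for proplatelet cytoskeleton, 5 and 3 for SRF targets, 11 and 8 for integrins, 7 and 9 for thrombopoietin and JAK-STAT genes, 7 and 4 for NF-κB genes, 7 and 6 for the BCL2 family, 2 and 11 for glycolysis, 9 and 6 for ribosome biogenesis and 5 and 2 for MELK partners. With the added number modelled, 10 were higher and 7 lower of 25 megakaryocyte and platelet markers, 1 and 14 of 23 erythroid markers, 4 and 8 of 19 granulocyte and monocyte markers, 11 and 0 of 17 cyclin-dependent kinase inhibitors and antiproliferative genes, and 7 and 7 of 24 p53 targets.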

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

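The GC and length correction, the minimum mean of 500 counts and the model of the added number were chosen after the values were seen, and the bounds for the splits were written after their counts. The count of changed genes was 4683, with 2297 higher and 2386 lower. DESeq2 gave 9858 (4931 higher, 4927 lower), of which 3609 hold only the 5 added values. The test against 1.5-fold gave 1180 (525 and 655), as its stricter null does by construction. The model of the added number, with the same dispersion for every gene, gave 9811 (4925 and 4886). Under the other alternatives the total stayed within 1.5 times, and leaving out 1 library gave 3591 to 3951. Without 1 library, 18233 to 18381 of the genes tested hold only the 5 added values, against 8895 with all 6. The lower totals may thus not come from the missing library alone. The balance of calls turned to 2699 higher and 2073 lower with library size alone, and to 1676 higher and 2275 lower without control replicate 2. Same-numbered libraries did not clearly deviate together (correlations 0.0998, -0.0124 and -0.0801), and not every library correlated best with its own number. These few weak correlations gave no clear sign of pairing but cannot exclude it. With the replicate block 4182 genes passed, and 3935 at a mean of at least 500 counts. Of the 10 splits of the 6 libraries, 1, the real one, gave as many genes (4683, highest other 0; 3877 and 0 at a mean of at least 500 counts), and 10 splits are too few for a share under 0.05. The other splits all mix control and knockdown libraries, so the difference between the groups counts as spread within theirs. Their 0 calls are thus no evidence against chance.

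MELK did not pass at -1.98 but passed with no filter (-1.98), at 5 CPM in 3 libraries (-1.99), with limma-voom (-2.48) and with the added number modelled (-3.38); leaving out 1 library gave -3.33 (without knockdown replicate 2, past the threshold) to -1.59. Of 29 lists, 9 passed. Without control replicate 2, 1 further list passed and 2 lost their call. With an estimated correlation 0 passed. For erythroid markers, cyclin-dependent kinase inhibitors and the stress response list, the estimated correlation (3.83e-05, -0.0189 and -0.00623) was below the preset 0.01. Their unadjusted camera p still rose (1.59e-07 to 0.00449, 2.08e-07 to 0.00501, 0.00215 to 0.0275), as for G2/M at 0.0106 (0.00802 to 0.0581). Correlation between members thus did not end these calls. At a mean of at least 500 counts 23 lists had enough members, and 0 of them passed with an estimated correlation, 3 with the preset and 22 with fry; fry on all tested genes gave 27, as it does not compare a list with other genes. GP9 reversed with the added number modelled (-1.51). With fry at a mean of at least 500 counts, integrins and focal adhesion (adjusted p = 0.00425) and NF-κB genes (0.0154) reversed. The cause was not tested. Among single named genes, 2700 of the gene and setting pairs kept direction and side, and 76 lost their call, 51 of them in the test against 1.5-fold. The simulated counts held fewer changed genes than the data. With the added number the edgeR fit recovered 41.8% of changes of 0.5 on the log2 scale among all tested genes. At a mean of at least 500 counts the share was 97.9%. Without the added number it was 97.1% among all tested genes, which were fewer (16469 against 30036).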

Other observations

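The tests of the added number and the count of genes that carry the word below were chosen after the values were seen. So were the gene lists of the first paragraph. The tests of GC content and of the word scan were written before their results.

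Members of 6 further gene groups are described at a mean of at least 500 counts. The groups were chosen with the leading genes in view, so a list test on them is no independent evidence. At the preset correlation of 0.01 all but the respiratory chain genes passed camera (adjusted p of 1.7e-07 to 0.0125). With an estimated correlation none passed camera (adjusted p of 0.0580 to 0.908). Of 12 heat shock chaperones, 11 rose and 1 fell (median log2 fold change 0.93). HSPA1B rose by 2.37 ± 0.05, HSPE1 by 1.63 ± 0.10 and DNAJA1 by 1.30 ± 0.06, and HSPB1 fell by 0.47 ± 0.04. HSPA1A and HSPA1B are near-identical copies that can share reads. Of 27 proteasome subunits, 22 rose and 4 fell. Of 10 matrix proteases and inhibitors, among them TFPI2, A2M and MMP1, 7 rose and 2 fell, and TIMP3 (-1.22 ± 0.03) and SERPINE2 (-0.97 ± 0.06) were the 2 that fell. Of 76 cytosolic ribosomal protein genes, 44 fell and 15 rose with a median of -0.15. Of 62 nuclear respiratory chain genes, 30 rose and 21 fell. Of 3 measured genes of class II antigen presentation, HLA-DRA (-2.44 ± 0.09) and CD74 (-2.22 ± 0.06) fell and CTSS rose (0.43 ± 0.09).

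The 5 values that make up 57.9% of the genes were weighed first. Low expression or ambiguous mapping would make 100 rarer than 10, but the ratio of their shares was 0.998. An added random number may account for them, since genes with a median of 100 to 200 counts, where it cannot be read off, had a mean excess variance between replicates of 1831, close to what the 5 numbers bring. Where it was added stays open. No biological explanation was tested.

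Most genes with a mean of at least 500 counts passed the threshold. Across genes, which are not independent replicates, log2 fold change went with GC content (Spearman rho -0.386) and hardly with length (0.0331). After each library's GC and length trend was removed, 3844 genes passed against 3873 before, which argues against that trend as the source of the number of calls. It does bear on which genes pass: 3227 passed both times, 3157 of them in the same direction. Whether the GC trend is technical or part of the response stays open, as does MELK loss itself. All 6 libraries carry 1 batch label.

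A candidate explanation for part of the decreases is repression of other transcripts by the hairpin through short matches. Over 15992 words of 7 bases in the 3′ UTRs of 4908 genes, the word most associated with lower expression was TGACTAT (t = -7.88; lowest of 200 shuffles -5.33; most positive word 3.80). The next 2 words overlap it, and the 3 join to TTGACTATA, which occurs once in MELK transcripts, in the coding sequence, at chromosome 9, 36594650 to 36594658 (GRCh38, plus strand, exon 5 of 18 in the longest transcript); 17.0% of scanned words occur in a MELK transcript. Genes with the word were lower by a log2 difference of -0.254 ± 0.0322 (SE) at equal UTR length and GC content, while the unadjusted medians were -0.042 with the word and 0.0059 without. Of the genes that fell by 2-fold or more, 11.4% carry it in the 3′ UTR against 7.54% of the others (Fisher's exact test, two-sided p = 0.0296). Anywhere in a transcript, 25.6% against 17.9% carry it. By bounds written after the values were seen, this count could not decide whether the word is the main source of the large decreases. Most genes that fell by 2-fold or more do not carry the word, though, which argues against that role. Other matches of the hairpin were not counted. The word was picked for the lowest t on these same fold changes. Fisher's test and the log2 difference are therefore no independent evidence, and the difference may be too large. Of the 10 largest decreases, 9 had a 3′ UTR to search, and 0 of the 9 carry the word there. The hairpin sequence is not given in the sources used here, another regulator that binds the same word was not tested, and with 1 hairpin and no rescue, effects of MELK loss and of the hairpin cannot be separated in these data.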
